A study of Rattus norvegicus with 12 samples.

How the data were processed

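Hippocampal RNA from 12 adult male rats was hybridised to Affymetrix Rat Expression Set 230 A arrays, 1 rat per array, with 6 rats of each line. Per the labels' protocols, total RNA was extracted with TRIzol and purified on columns, its quality was read on a Bioanalyzer, and hippocampus and cortex samples were run as one batch. The deposited values are log2 expression that the authors made with RMA, which corrects background, normalizes by quantiles and summarizes probes, in affy 1.54.0 per the submitters' processing notes, with a custom probe definition (version 19.0.0) that assigns probes to Entrez genes, per the series' design text. Values of single probes were not used here, so a probe that matches a sequence variant of one line could not be seen.

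The table holds 10019 probe sets in 12 columns, all matched to samples. The 57 control probe sets were left out of the tests and 9962 genes were tested. The number before the suffix of each name was matched to the RefSeq gene table of assembly GRCr8, which named 9831; the platform annotation gave 1 symbol for 9515 and several for 0. Both gave a name for 9498, of which 9075 were identical and 9490 were identical or a listed synonym. The RefSeq symbol was used first, and 114 genes stayed unnamed but in the tests. No build is named for the values, so no coordinates are given and the RefSeq table served for names and gene order only. Array values have no read depth; the precision of a mean is limited by the 5 arrays per line.

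Line was taken from the labels. The 2 arrays that the submitters marked as failed were left out of the main comparisons, which leaves 10. The design text gives a sample-sample correlation of about 0.66 for both; in the deposited values bHR replicate 1 had 0.658 to 0.697 with the passing arrays and bLR replicate 5 had 0.882 to 0.908. Replicates are numbered in accession order. Differences are bHR minus bLR throughout, on the log2 scale. Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, with Benjamini-Hochberg adjustment over all 9962 genes), with line as the only term. The slope on locomotor score was fitted per 100 beam breaks with line as a term and the score centred within line. Of 38 gene lists, 36 had at least 5 measured members and were tested with camera (preset correlation 0.01), with camera at an estimated correlation, and with fry. Adjusted p of lists are over the 36 lists. Lists cover cell types of the hippocampus and of neighbouring tissue, signalling and metabolic processes, and genes recalled from later analyses of these lines. Locomotor scores and control signals were compared by two-sided exact permutation tests, and correlations between arrays used 100000 permutations, of which the smallest possible p is 1e-05. Neighbouring genes were compared with 10000 random sets of 100 genes.

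Loss of 5' signal was measured as the 5' minus 3' log2 value of control probe sets. These were for beta-actin and GAPDH, for dap, a bacterial control RNA, and for cre, a hybridisation control. The genes named are the 24 with the smallest p (since none passed), up to 4 members with the smallest p of each list described, all members of the list from later analyses, and the longest runs of neighbours among the 100 first-ranked genes, which were 5 pairs; other genes named were chosen after their values were seen: Ttr, the genes flanking Pgk1, and the 2 genes with the smallest p for the slope on locomotor score.

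The steps were tested on simulated data in which 200 genes were changed. In that simulation of bHR against bLR with 9962 genes, limma recovered 55 of 67 genes changed by 0.5 on the log2 scale, 66 of 67 changed by 1 and 66 of 66 changed by 2, with 16 false calls. Without any change it called 0 genes, and 492 had an unadjusted p under 0.05. The alternatives, fixed before the data were examined, were all 12 arrays with and without array weights, each array left out in turn, the lowest 25% of genes left out, quantile normalization repeated, median centring, a trended and robust prior, the first component of the residuals as a covariate, the number in the sample titles as a block, other adjusted p thresholds and other sizes of the neighbour test. A further 3 were chosen after seeing the data: the beta-actin 5' minus 3' value as a covariate, the log2 level of Ttr as a covariate, and leaving out the 3 arrays with the lowest dap value.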

Results

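RNA of the whole hippocampus was profiled in adult male rats of the 4th generation of 2 selectively bred lines, 1 rat per array. Bred High Responder (bHR) rats descend from animals that moved a lot in an unfamiliar environment, and bred Low Responder (bLR) rats from animals that moved little. There were 6 arrays per line. The submitters marked 1 array of each line as having failed quality control, bHR replicate 1 and bLR replicate 5, which left 5 arrays per line for the comparisons. Expression was given as log2 values for 9962 genes, measured on an Affymetrix array whose probes had been assigned to 1 probe set per gene. The number of arrays limits the precision of every value.

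The lines differed widely in the behaviour they were bred for. Over the 12 rats, bHR made 1245 ± 64.8 beam breaks in an unfamiliar environment (SD, n = 6) and bLR made 463 ± 98.3 (SD, n = 6). The difference was 782 beam breaks, and the lowest bHR score, 1178, lay above the highest bLR score, 557 (two-sided exact permutation test, p = 0.0022, the smallest that 6 against 6 allows). Among the 10 rats whose arrays passed, the difference was 809 beam breaks (two-sided exact permutation test, p = 0.0079, the smallest that 5 against 5 allows).

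Signs of RNA quality differed between arrays within both lines. The beta-actin transcript gave less signal from its 5' than from its 3' control probe set on every array, and the loss was deepest on bLR replicate 3 (-3.65 on the log2 scale), bLR replicate 2 (-2.89) and bHR replicate 6 (-2.30). It lay between -1.95 and -1.36 on the other 7 passing arrays. For GAPDH, a second transcript of the tissue, the 5' minus 3' value was -1.25 on bLR replicate 3 and -0.54 on bLR replicate 2. It was only -0.0012 on bHR replicate 6, against 0.12 to 0.34 on the other 7, so the loss on bHR replicate 6 was slight by this measure. Per line, the 5' minus 3' value of beta-actin was -1.76 ± 0.36 in bHR and -2.21 ± 1.01 in bLR (SD, n = 5 each), a difference of 0.44 (two-sided exact permutation test, p = 0.437). The same 3 arrays had the lowest 5' minus 3' values of dap, a bacterial control RNA, at -1.82, -1.54 and -1.36, against -0.42 to -0.07 on the others. The first principal component of the 10 arrays held 45.4% of the variance and followed the beta-actin value (Pearson r = -0.981, permutation p = 2e-05; Spearman's rho = -0.891, permutation p = 0.00096). Without the 2 arrays farthest from the median, bLR replicates 2 and 3, r was -0.958. After Benjamini-Hochberg adjustment over the 3 relations computed, these p-values were 3e-05 and 0.00144. The 2 failed arrays correlated less with the rest: the mean Pearson r with the other 11 arrays was 0.700 for bHR replicate 1 and 0.896 for bLR replicate 5, against 0.946 to 0.958 for the passing arrays.

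**Figure D1:**
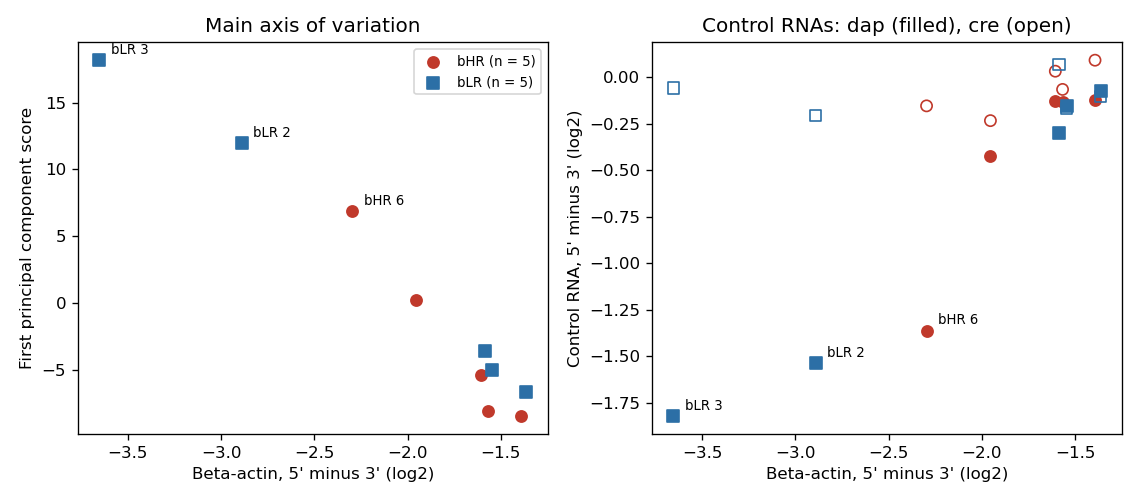
Each point is one of the 10 passing arrays (circles bHR, squares bLR); the x axes give the 5' minus 3' log2 signal of the beta-actin control probe sets. The left panel plots the first principal component score, which rises from -8.49 to 18.2 as the 5' signal falls, and the right panel plots the 5' minus 3' log2 signal of the control RNAs dap (filled) and cre (open), of which dap falls to -1.82 and cre does not fall below -0.23.

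The comparison of bHR with bLR asked which hippocampal genes differ between rats bred for high and for low exploratory activity. Pgk1, an enzyme of glycolysis encoded on the X chromosome, stood first in the ranking, with a log2 level of 9.79 ± 0.097 in bHR and 9.33 ± 0.14 in bLR (SD, n = 5 each). The difference was 0.45 on the log2 scale (SE 0.071), and all bHR arrays lay above all bLR arrays. Taf9b, a subunit of a general transcription complex, stood second, with 4.56 ± 0.051 in bHR and 4.36 ± 0.051 in bLR, also without overlap. Its signal was low: 6.35% of the genes had a lower mean. Neither passed the test over all genes: the limma adjusted p was 0.506 for Pgk1 and 0.992 for Taf9b. With all 12 arrays, the failed ones included, the Pgk1 difference was -0.028.

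No gene passed an adjusted p of 0.05 with limma (0 of 9962), and 0 passed 0.10. At an unadjusted p under 0.05 limma gave 293 genes, of which 110 were higher and 183 lower in bHR, where chance alone gives about 498. With a trended and robust prior, limma gave 0 genes after adjustment and 265 at an unadjusted p under 0.05. The lines did not overlap for 29 genes, 0.291% of those measured, where chance gives 0.794% on average. Most differences were small: 9680 genes (97.2%) differed by less than 0.2 on the log2 scale, and for 9929 genes (99.7%) the 95% confidence interval excluded a 2-fold difference in either direction. On simulated arrays with the same means and spreads and independent genes, 82.1% of genes changed by 0.5 on the log2 scale and 98.5% of genes changed by 1 were recovered. There, 200 genes were changed at once, which eases the adjusted threshold. These rates therefore do not hold where fewer genes differ, which was not simulated.

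The 24 first-ranked genes, given as values that did not pass, comprised 7 with a higher mean in bHR and 17 with a lower one, and their unadjusted limma p reached up to 0.0069. Besides Pgk1 and Taf9b, the means were higher in bHR for Eml1, a microtubule-binding protein, by 0.48 (SE 0.13), for Lama3, a laminin chain, by 0.14, for Tom1l2 by 0.20, for Cfap90 by 0.20 and for Bmp3, a secreted BMP-family ligand, by 0.18. Among those with a lower mean in bHR, Nhsl2 had the widest difference, -0.61 on the log2 scale (SE 0.17), and -0.35 without the 3 arrays with the lowest dap value. Akap5, which anchors kinases at the postsynaptic membrane, differed by -0.20 (SE 0.049), Slc30a9, a zinc transporter, by -0.31, and Nudt4, a hydrolase of inositol pyrophosphates, by -0.22. Uqcr11, a subunit of complex III, differed by -0.15, Uqcc2, an assembly factor of that complex, by -0.27, Mrpl54, a mitochondrial ribosomal protein, by -0.23, Eif3f, a translation initiation factor, by -0.17 and Snrpb2, a spliceosomal protein, by -0.18. The values for the others were -0.33 for Mphosph6, -0.26 for Smim29, -0.24 for Entpd4, -0.20 for Fam89b, -0.20 for Cmss1, -0.19 for Ssna1, -0.19 for Uspl1 and -0.15 for Zfp213.

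**Figure D2:**
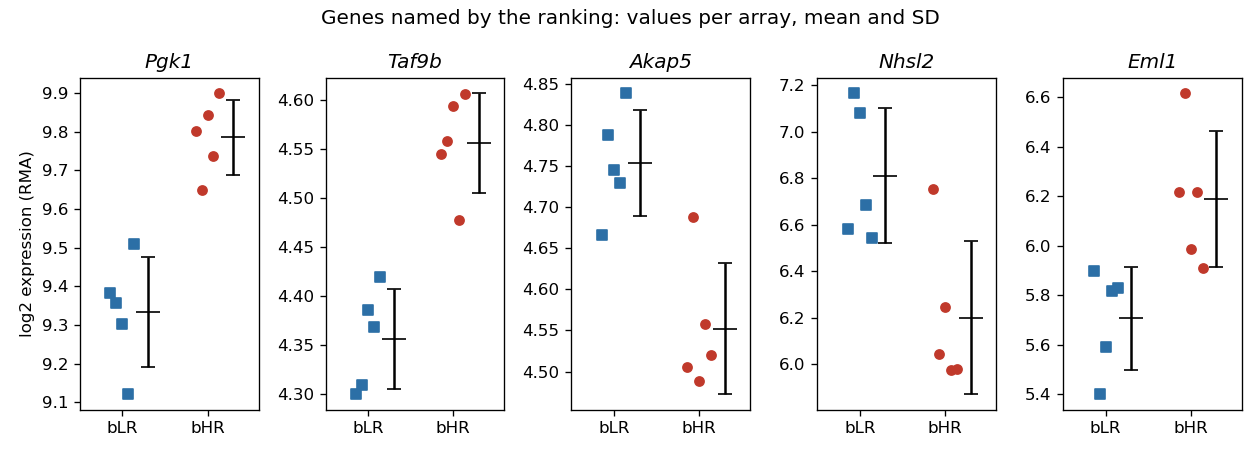
Log2 expression of Pgk1, Taf9b, Akap5, Nhsl2 and Eml1 on each of the 10 passing arrays (squares bLR, circles bHR; n = 5 per line), with the mean (horizontal mark) and SD (bar) of each line; each y axis has its own range. The lines do not overlap for Pgk1, Taf9b and Eml1 and overlap for Akap5 and Nhsl2.

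Sets of genes were compared next. Of 36 lists fixed before the data were examined and holding at least 5 measured members, 3 were shifted upward in bHR relative to other genes by camera with a preset correlation of 0.01 between genes: the choroid plexus markers (adjusted p = 0.00573), the MHC and antigen presentation genes (adjusted p = 0.0384) and the monoamine and acetylcholine receptors and transporters (adjusted p = 0.0384). With a correlation estimated from the data none of the 36 was called: the adjusted p was 0.926 for each of the 3. The directional test of fry, which asks whether the members move one way on balance, gave an adjusted p of 0.967 for each. In no list did a member pass over all genes, and adjusted over the list alone 1 member did in all lists together, Pgk1 in the glycolysis list (adjusted p = 0.00051).

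The choroid plexus markers label the epithelium that makes cerebrospinal fluid and that borders the hippocampus. Of 14 measured members 12 had a higher mean in bHR and 2 a lower one, 0 passed the test, and the median difference was 0.081. The signal was low for 6 of the 14, whose means lie in the lowest 25% of genes, and with that part of the genes left out the median was 0.155 (adjusted p = 0.000138). The members with the smallest unadjusted p were Cab39l, which differed by 0.14, Enpp2, which makes lysophosphatidic acid and is also expressed by oligodendrocytes, by 0.54 (SE 0.21), Slc13a4, a sulphate transporter, by 0.15, and Sostdc1, a secreted antagonist of BMP and Wnt ligands, by 0.27. Without bHR replicate 5 Slc13a4 differed by 0.091 and Sostdc1 by 0.15. Ttr, which encodes transthyretin, was singled out after its values were seen. It had the widest difference of all 9962 genes, 1.91 on the log2 scale (SE 1.19), and the spread within lines was as wide: 9.44 ± 2.13 in bHR and 7.53 ± 2.32 in bLR (SD, n = 5 each; two-sided exact permutation test, p = 0.190). The call of this list ended without bHR replicate 5 (median 0.055, adjusted p = 0.0926) and without bLR replicate 6, where the median was little changed (0.075, adjusted p = 0.0503). It also ended with the log2 level of Ttr as a covariate and Ttr itself left out (median 0.034, adjusted p = 0.405). With that covariate Cab39l differed by 0.15, Enpp2 by 0.26, Slc13a4 by 0.076 and Sostdc1 by 0.043.

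**Figure D3:**
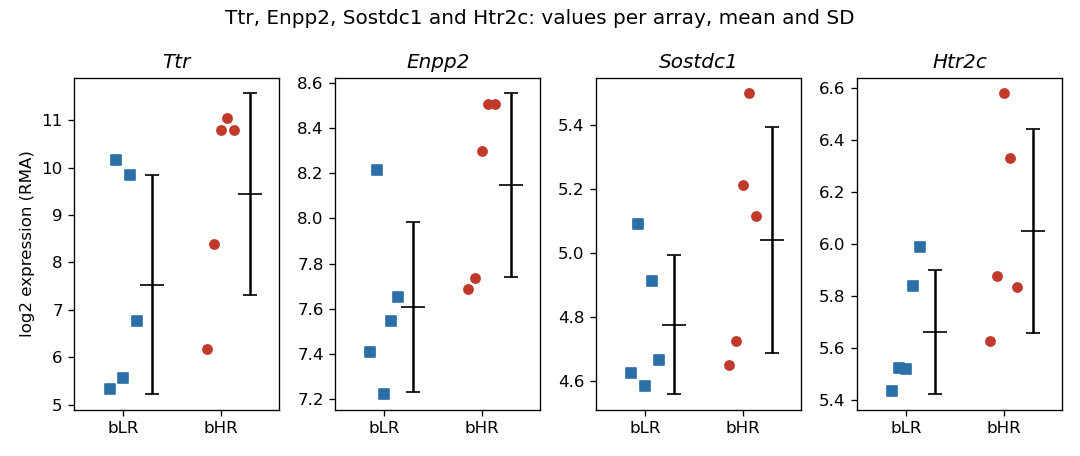
Log2 expression of Ttr, Enpp2, Sostdc1 and Htr2c on each of the 10 passing arrays (squares bLR, circles bHR; n = 5 per line), with the mean (horizontal mark) and SD (bar) of each line; each y axis has its own range. Ttr runs from 5.34 to 10.2 in bLR and from 6.17 to 11.1 in bHR, so that the lines overlap for all 4 genes.

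Of 16 measured MHC and antigen presentation genes, 13 had a higher mean in bHR and 3 a lower one, 0 passed, and the median difference was 0.047. RT1-A2, a class I gene, differed by 0.44 (SE 0.18), RT1-Da, a class II chain, by 0.082, Cd74, the class II invariant chain, by 0.070 and RT1-CE5 by 0.046. RT1-Da differed by 0.048 without bHR replicate 5, and Cd74 by 0.032 without bHR replicate 2. The signal was low for most: 13 of the 16 lay below the median gene, and probes of this gene family can bind related members, so the values of single RT1 genes are uncertain. With the lowest 25% of genes left out the list was no longer called (median 0.080, adjusted p = 0.1001). Of 40 monoamine and acetylcholine receptors and transporters, 32 had a higher mean in bHR and 8 a lower one, 0 passed, and the median difference was 0.031. That median depended on single arrays: it was 0.011 without bHR replicate 2, 0.020 without bLR replicate 3, 0.020 without bHR replicate 4 and 0.057 without bHR replicate 6. It was 0.047 with the Ttr covariate and 0.057 with all 12 arrays. With the lowest 25% of genes left out this list was no longer called (adjusted p = 0.298), though its median, 0.029, was little changed. The serotonin receptor Htr2c, which choroid plexus also expresses strongly, differed by 0.39, the noradrenaline receptors Adra1b and Adra2a by 0.098 and 0.10, and the noradrenaline transporter Slc6a2 by 0.12. Htr2c differed by 0.26 without bHR replicate 4, and Slc6a2 by 0.079 without bLR replicate 2. With the Ttr covariate Htr2c differed by 0.24, Adra1b by 0.082, Adra2a by 0.11 and Slc6a2 by 0.16. Within lines, over the 10 arrays, the mean level of this list correlated with the 5' minus 3' value of beta-actin by Pearson's r (0.697, permutation p = 0.0259, adjusted over 3 relations 0.0388) and not by Spearman's rho (0.491, permutation p = 0.154, adjusted 0.231). Without bLR replicates 2 and 3 r was 0.728. For the MHC list r was 0.244 (permutation p = 0.495) and rho 0.152 (permutation p = 0.683), and r was 0.168 without those arrays. Such an r was computed for all 38 lists, so the adjustment over 3 relations does not cover every comparison made. With the beta-actin value as a covariate, the adjusted p was 0.674 for the receptors and 0.0731 for the MHC genes (medians 0.0087 and 0.038). Without the 3 arrays with the lowest dap value the calls were lost too, with an adjusted p of 0.209 and 0.137, while the medians, 0.043 and 0.051, were no smaller than with all 10 arrays. Each of the 2 calls was kept in 2 of the 10 fits that leave out 1 array: that of the MHC genes without bLR replicate 1 or bHR replicate 4 (adjusted p = 0.0536 to 0.126 in the other 8), and that of the receptors without bLR replicate 1 or bHR replicate 6 (0.0769 to 0.537 in the other 8). Over the 10 fits the MHC median ran from 0.032 to 0.057, so a lost call there does not mean that the shift went away.

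The other 33 lists were not called, with medians from -0.031 to 0.051. Of 26 BMP and TGF-beta signalling genes 20 had a higher mean in bHR and 6 a lower one (median 0.044, adjusted p = 0.110), and 0 passed. The list was called with all 12 arrays (adjusted p = 0.0123), with the lowest 25% of genes left out (0.0227) and without bHR replicate 6 (0.0379). Its median was 0.021 without bHR replicate 4, 0.024 without bLR replicate 3 and 0.025 with the beta-actin covariate, and 0.067 with all 12 arrays. Besides Bmp3, Smad1 differed by -0.092, Bmp4 by -0.13 and the receptor Bmpr1a by 0.21 (0.13 without bLR replicate 2). Of 19 interneuron markers 13 were higher and 6 lower, 0 passed (median 0.047, adjusted p = 0.110), with differences of 0.19 for Reln, 0.11 for Npy2r, 0.090 for Tac1 and 0.19 for Sst. Tac1 differed by 0.049 without bHR replicate 5, and Sst by 0.11 without bHR replicate 6, by 0.075 with the Ttr covariate and by 0.046 without the 3 arrays with the lowest dap value. Single arrays decided its call: it was called without bHR replicate 2 (adjusted p = 0.0132) or without bLR replicate 6 (0.0109). Its median was 0.027 without bLR replicate 3, 0.077 without bLR replicate 1 and 0.084 without bHR replicate 6, and it was 0.022 with the beta-actin covariate, 0.029 with the Ttr covariate and 0.031 without the 3 arrays with the lowest dap value. Of 17 oligodendrocyte markers 10 were higher and 7 lower, 0 passed (median 0.051, adjusted p = 0.334), with Enpp2 shared with the choroid plexus list, Mal at 0.30, Myrf at -0.15 and Car2 at 0.26. It was called without bHR replicate 4 (adjusted p = 0.0131) and with the Ttr covariate (0.0267), and leaving out 1 array moved its median from -0.010 (without bHR replicate 2) to 0.11 (without bHR replicate 4). Mal differed by 0.19 without bHR replicate 6, and without bLR replicate 3 Myrf differed by -0.088 and Car2 by 0.11.

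Of 10 glycolysis genes 7 were higher and 3 lower (median 0.017, adjusted p = 0.374). None passed over all genes, and besides Pgk1, Hk1 differed by 0.16, Aldoc by -0.025 and Slc2a1 by -0.021. The values of these 3 rested on single arrays: leaving out 1 gave 0.0076 (without bLR replicate 3) to 0.26 (without bLR replicate 6) for Hk1, -0.054 (without bHR replicate 3) to 0.0010 (without bHR replicate 6) for Aldoc and -0.046 (without bHR replicate 5) to 0.0061 (without bHR replicate 4) for Slc2a1. Hk1 was -0.053 with the beta-actin covariate. Leaving out 1 array moved the median from -0.0068 (without bLR replicate 1) to 0.046 (without bLR replicate 6). Of 39 respiratory chain genes 23 were higher and 16 lower, 0 passed (median 0.013, adjusted p = 0.896), with -0.099 for Cox6a1, -0.12 for Cox5b, 0.16 for Uqcrfs1 and 0.24 for Sdha. Without bLR replicate 3 Uqcrfs1 differed by 0.093 and Sdha by 0.10, Cox5b differed by -0.074 without bLR replicate 2 and by -0.075 without bHR replicate 4, and with all 12 arrays Sdha differed by 0.022 and Uqcrfs1 by -0.041. Over all alternatives Cox6a1 ran from -0.29 to -0.069 and Cox5b from -0.32 to -0.045. This list was called in the opposite direction, lower in bHR, with all 12 arrays (median -0.15, adjusted p = 0.00287) and without the 3 arrays with the lowest dap value (median -0.048, adjusted p = 0.00863), and leaving out 1 array moved its median from -0.015 (without bLR replicate 3) to 0.037 (without bLR replicate 6). The 20 microglial markers were split into 9 higher and 11 lower, 0 passed (median -0.016, adjusted p = 0.896), with -0.14 for C1qa, -0.15 for P2ry12, 0.078 for Cd14 and 0.14 for C1qb, and leaving out 1 array moved the median from -0.025 (without bLR replicate 6) to 0.0089 (without bLR replicate 2). C1qa differed by -0.088 and Cd14 by 0.041 without bLR replicate 2, P2ry12 by -0.080 and Cd14 by 0.048 without bHR replicate 5, and C1qb by 0.053 without bLR replicate 3.

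One list was recalled from later analyses of these lines that included these arrays, so it is not independent evidence of its direction. It held 25 genes, of which only 13 were measured here. Of its 13 measured genes 8 had a higher mean in bHR and 5 a lower one, and 0 passed over all genes or adjusted over the list alone (smallest adjusted p over the list 0.271). Its median was 0.024 and its mean -0.0018, and camera, which pointed upward, gave an adjusted p of 0.896. Leaving out 1 array moved the median from -0.0021 (without bLR replicate 6) to 0.029 (without bLR replicate 1). Camera pointed downward without bHR replicate 3, bHR replicate 4 or bLR replicate 6. The complement component C1qa differed by -0.14 (SE 0.059), Bmp4 by -0.13 (SE 0.062), Tdg by -0.15 (SE 0.074) and Exosc7 by 0.12 (SE 0.062). The values for the others were 0.064 for Trhr, 0.10 for Mfge8, 0.056 for Acox3, -0.034 for Ghdc, 0.024 for Pex11a, 0.032 for Ncan, 0.027 for Apln, 0.0046 for Fzd6 and -0.0033 for Ucp2.

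Locomotor score was also related to expression among rats of the same line. No gene passed an adjusted p of 0.05 with limma (0 of 9962, smallest adjusted p 0.947). At an unadjusted p under 0.05 there were 410 genes, 167 with a positive and 243 with a negative slope. Chance gives about 498 on average, and how widely that count varies on these arrays was not measured for the slope. The smallest unadjusted p were those of Srp19, a protein of the signal recognition particle, at -0.18 per 100 beam breaks on the log2 scale (SE 0.034), and of Hdhd2, at 0.22 (SE 0.042), neither past the test. With the first component of the residuals as a covariate, limma gave 0 genes after adjustment and 877 at an unadjusted p under 0.05. That component leaves the slopes unchanged and lowers only the residual variance, so the higher count is not evidence of a relation to the score. The limma count moved both ways elsewhere. It was 924 with all 12 arrays and array weights (smallest adjusted p 0.0781), 769 with the beta-actin covariate and 208 without bLR replicate 6. The lowest bLR score (319, bLR replicate 3) and the highest bHR score (1328, bHR replicate 6) fell on arrays with deep loss of beta-actin 5' signal. Score and array quality are thus partly mixed.

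Genes that lie next to each other were looked for among the 100 first-ranked genes, by gene order in the RefSeq assembly GRCr8. Of these, 10 had another among the 3 next measured genes, where random sets held 5.82 on average (permutation test, p = 0.148). They formed 5 pairs: Pgk1 and Taf9b, which are adjacent on the X chromosome, Uqcc2 (-0.27) and Smim29 (-0.26), Mrpl54 (-0.23) and Nmrk2 (0.15), Rasl10a (-0.24) and Nefh (-0.19), and Ica1 (-0.19) and Nxph1 (0.34). The measured genes on either side of Pgk1 and Taf9b differed little: 0.012 for Atp7a and 0.023 for Magt1 before them, and -0.026 for Cysltr1 and -0.013 for Pou3f4 after them. Among the 50 first-ranked genes 6 had a neighbour (permutation p = 0.0324), and among 200 genes 23 did (p = 0.506).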

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

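The tests of the 5' signal loss and of neighbouring positions, and those of choroid plexus tissue and of the beta-actin covariate, were chosen after the results were seen; the counts over other splits of the arrays were planned. Single arrays lay far from the other arrays of their line in 9 of 146 groups of values, where about 7.3 were expected by chance. Many of the groups are of genes named for a small p on the same arrays, so that figure is only a rough guide. Both failed arrays were among them: the mean correlation with the other 11 arrays was 0.700 for bHR replicate 1, with the next bHR array at 0.951, and 0.896 for bLR replicate 5, with the next bLR array at 0.946. The submitters had already marked both as failed, so these flags are not a new result. The 5' minus 3' value of dap on bHR replicate 6 was -1.36, with the next bHR array at -0.42. On bHR replicate 6 Slc30a9 was 7.49 against at most 7.27 on the other bHR arrays, and on bHR replicate 5 Tac1 was 5.13 against at most 4.96. On bHR replicate 4 C1qa was 7.07 against at least 7.19. On bLR replicate 2 Snrpb2 was 6.07 and Uqcc2 7.46, against at most 5.94 and 7.12 on the other bLR arrays, and on bLR replicate 6 Nmrk2 was 4.54 against at least 4.68.

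Of 100 splits of the 10 arrays, the real one included, the others gave up to 11 genes past an adjusted p of 0.05; that 100 reach the real count of 0 is fixed in advance and says nothing. At an unadjusted p under 0.05, 65 of the 100 gave at least the real 293 genes, the highest of the others being 1930. The 16 splits with the 3 arrays with the lowest dap value on one side had a median of 1209.5 such genes and the others 335, which points to a structure of the arrays. At least 1 list was called in 73 of the 100. As many lists as the real 3 were called in 31 of the 100, at most 8, so chance is not excluded for the count of lists or for the 293 genes.

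The first pattern is the loss of 5' signal that the main axis of variation follows. Dap, a bacterial RNA that is not in the tissue, lost 5' signal on the same arrays (r with beta-actin 0.954 over the 10 arrays, and 0.876 within the 7 arrays other than bLR replicates 2 and 3 and bHR replicate 6). If the dap signal came from added RNA, this argues against degradation in the tissue before that addition as the whole cause. On the failed arrays bHR replicate 1 and bLR replicate 5 the 5' minus 3' value of dap was 1.04 and 0.979. The lines alone are argued against too, since the component followed the beta-actin value within lines (r = -0.979). Shorter copies made during labelling remain a candidate explanation: cre, a hybridisation control, ranged over only 0.186 of the range of dap. That comparison assumes that cre was added after labelling. The controls also differed in level, with a mean of 12.3 for the cre 3' probe set against 7.04 and 6.43 for the dap 3' and 5' probe sets. Their ranges were thus not compared at like signal, and the ratio cannot decide. The sources used here do not state how the control RNAs were added.

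The second pattern is the choroid plexus list. Unequal 5' signal loss is argued against, since the list kept an adjusted p of 0.00918 and a median of 0.085 with the beta-actin value as a covariate. Choroid plexus carried over at dissection, in amounts that differ between animals, may account for it: within lines, the median correlation of the 13 other members with Ttr was 0.505, 10 of the 13 correlated positively, and Ttr spanned 28.3-fold among bLR arrays alone. The correlation was not set against that of other genes. Members that vary together between animals for any reason would give it, so it cannot single out carried-over tissue. Chance cannot be excluded, since 8 of 100 splits of the 10 arrays, the real one included, gave the list a camera p of at most the real 0.000159, the smallest of the others being 2.6e-08. A line difference in choroid plexus itself was not tested and stays open.

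The third pattern is Pgk1 and Taf9b, adjacent genes ranked first and second. Unequal 5' signal loss is argued against, because the Pgk1 difference was 0.449 with the beta-actin value as a covariate and 0.45 without it. Of all pairs of measured genes, a share of 0.000608 lies within 3 genes of each other, but the pair was noticed before this share was computed, so the share does not exclude neighbours by chance. A linked difference between the lines may be a candidate explanation and stays open: over the 100 first-ranked genes the neighbour count gave a permutation p of 0.148, and with 50 or 200 genes 0.0324 and 0.506. A sequence variant under the probes, and cross-hybridisation of related sequences, were not tested.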

How the results depend on the processing

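The covariates beta-actin and Ttr and the omission of the 3 arrays with the lowest dap value were chosen after seeing the data. No alternative gave a gene past an adjusted p of 0.05 with limma, for the lines or for locomotor score (0 in each, leaving out each array included; 42 to 1468 and 45 to 924 genes at an unadjusted p under 0.05). The number in the sample titles as a replicate block left 0 genes, with a smallest adjusted p of 0.0598 and 1468 at an unadjusted p under 0.05 on 2 residual degrees of freedom. Its line difference rests on 3 pairs of same-numbered arrays, since each other array has a number of its own. Deviations within the pairs correlated at -0.334, 0.263 and 0.409. The best bLR partner was the same-numbered array for bHR replicates 3 and 4, and bLR replicate 1 for bHR replicate 2. These values do not decide whether the numbers pair arrays, and the main fit did not pair them. The locomotor difference was 809 for 10 rats and 782 for 12. The number of called lists, 3, was 5 with all 12 arrays (BMP and the respiratory chain, lower in bHR, added), 1 with array weights, 1 after repeated quantile normalization and 1 with the beta-actin covariate (choroid plexus in each), and 0 with an estimated correlation or with fry. It was 2 with the lowest 25% of genes left out (choroid plexus and BMP). It was also 2 with the residual component, which leaves the line differences unchanged (choroid plexus and synaptic vesicle, adjusted p = 0.00225). It was 3 with the Ttr covariate (MHC, receptors and oligodendrocyte) and 3 without the 3 low-dap arrays (choroid plexus, with the respiratory chain and heat shock lists lower in bHR, adjusted p = 0.00863 and 0.0274). Leaving out 1 array gave 0 to 3: 0 without bHR replicate 5, 1 (choroid plexus) without bHR replicate 3 or bLR replicate 2, 3 or 4, and 1 (interneuron) without bLR replicate 6. Without bHR replicate 2 the 3 were choroid plexus, interneuron and neuropeptides. Over the refits the adjusted p of the choroid plexus list ran from 7.4e-05 to 0.405, of the MHC list from 0.0131 to 0.137 and of the receptor list from 0.0117 to 0.674. Neighbours numbered 6 among 50 genes and 23 among 200, as fewer or more genes were drawn, and 10 with gene families counted once.

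Of 1328 values of 67 of the named genes under 20 alternatives, 1316 kept their direction and none passed the test. Many of these genes were named for a small p on the same arrays, and the alternatives share most arrays with the main fit. The trended prior and the residual component cannot change a difference at all, so kept directions are largely built in. With all 12 arrays Pgk1 was -0.028, Car2 -0.066, Slc2a1 0.025 and Uqcrfs1 -0.041. Slc2a1 was 0.0016 after repeated quantile normalization, and Hk1 was -0.053 with the beta-actin covariate. Without the 3 low-dap arrays Syt4 was -0.082, Nsf -0.045, Hk1 -0.094 and Aldoc 0.027. Leaving out 1 array gave -0.046 to 0.0061 for Slc2a1 and -0.054 to 0.0010 for Aldoc. Medians were followed for 10 lists, and those that changed sign were, with all 12 arrays, -0.066 for oligodendrocyte, -0.11 for glycolysis and -0.15 for respiratory chain genes; with array weights, -0.0024 for glycolysis and -0.011 for the respiratory chain; with the beta-actin covariate, -0.011 for synaptic vesicle genes, 0.00087 for microglia and -0.011 for the respiratory chain; with the Ttr covariate, -0.0036 for glycolysis, 0.0013 for microglia and -0.027 for the respiratory chain; and without the 3 low-dap arrays, -0.025 for synaptic vesicle genes, 0.032 for microglia and -0.048 for the respiratory chain. Leaving out 1 array gave -0.010 to 0.11 for oligodendrocyte, -0.0068 to 0.046 for glycolysis, -0.025 to 0.0089 for microglia and -0.015 to 0.037 for respiratory chain medians. The cause was not tested, except that fewer arrays or genes enter some fits. Low signal limits the genes whose mean lies in the lowest 25%, below 4.83. Among those named, they include Taf9b, Akap5, Zfp213, Nmrk2, Npy2r, Adra1b, Adra2a, Bmp4, Cd14 and RT1-CE5, whose means were below that limit in both lines.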

Other observations

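Of 26 measured synaptic vesicle genes 15 had a higher mean in bHR and 11 a lower one, 0 passed, and the median was 0.026 (camera adjusted p = 0.334). With the first component of the residuals as a covariate the list was called higher in bHR (camera adjusted p = 0.00225). That component is taken from the residuals of the line model and cannot change a line difference, and the median stayed at 0.026. The call therefore reflects a smaller residual variance, not a larger difference. Nsf, the ATPase that recycles fusion complexes, had 9.35 ± 0.45 in bHR and 8.67 ± 1.27 in bLR (SD, n = 5 each), Sv2b, a vesicle membrane protein, 8.39 ± 0.42 and 7.70 ± 1.18, and Stx1a and Syt4 differed by 0.28 and 0.20. Within lines, the mean level of the list followed the 5' minus 3' value of beta-actin (Pearson r = 0.981 over the 10 arrays, permutation p = 1e-05, the smallest the permutations can give, rho = 0.952, permutation p = 7e-05, adjusted over 3 relations 3e-05 and 0.00021, r = 0.944 without bLR replicates 2 and 3). Such an r was computed for all 38 lists, and this one was the largest in size. It was -0.931 for the oligodendrocyte precursor list, 0.905 for the GABA receptors and 0.888 for the astrocyte list. The adjustment over 3 relations does not cover these. With the beta-actin value as a covariate the median of the synaptic vesicle list was -0.011 (camera adjusted p = 0.884), and Nsf differed by 0.13 and Sv2b by 0.18. Without the 3 arrays with the lowest dap value the median was -0.025 (adjusted p = 0.319), Nsf differed by -0.045 and Sv2b by 0.012. Leaving out 1 array gave medians from 0.0056 (without bLR replicate 3) to 0.061 (without bLR replicate 4), 0.22 to 0.94 for Nsf and 0.29 to 0.96 for Sv2b (each lowest without bLR replicate 3 and highest without bLR replicate 6). Stx1a differed by 0.13 without bLR replicate 3, and Syt4 by 0.10 without bLR replicate 2, 0.11 without bLR replicate 3 and 0.32 without bLR replicate 6.

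Of 9 dentate granule cell markers 4 had a higher mean in bHR and 5 a lower one, 0 passed (camera adjusted p = 0.896), with -0.24 for Rasl10a and -0.20 for Prox1. Of 14 pyramidal cell markers of CA1 and CA3 3 were higher and 11 lower, 0 passed (median -0.031, adjusted p = 0.738), and the median ran from -0.012 (without bLR replicate 3) to -0.055 (without bLR replicate 6) and was -0.10 with all 12 arrays. The glucocorticoid receptors and targets were split into 7 higher and 14 lower of 21 (median -0.018, adjusted p = 0.738), and the FGF and neurotrophin signalling genes into 14 and 14 of 28 (median 0.0014, adjusted p = 0.913); 0 passed in either. For the last of these the mean, -0.0060, and the test pointed down while the median was above 0, and this rested on single arrays: the median was -0.015 without bHR replicate 2, -0.0037 without bHR replicate 4 and -0.0073 without bLR replicate 6, and the test pointed up without bLR replicate 1 or 6 or bHR replicate 5 or 6. The glucocorticoid median ran from -0.0053 (without bLR replicate 4) to -0.036 (without bLR replicate 6) and was 0.015 with all 12 arrays.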
